A study of Homo sapiens with 4 samples.

How the data were processed

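Total RNA from human primordial germ cell-like cells derived from H1 embryonic stem cells, wild type or KLF4 knockout, was reverse transcribed and amplified with the NuGEN RNA-Seq System V2 and sequenced from a single end on a HiSeq4000, per the labels. The series holds 4 libraries, 2 per genotype, at 65 and 68, which the labels call passage number in one place and passage days in another. They are written as passages here. The deposited values are counts of reads per gene for each library, without normalization. Per the file headers, these counts were made by featureCounts 2.0.0 over exons grouped by gene symbol, skipping reads marked as duplicates. The command set no strand option and did not count reads that align to several places or overlap 2 genes. The processing notes also name FastQC, cutadapt 2.3, TopHat2 2.0.13 and the hg19 genome. Whether duplicates had been marked before counting is not stated. All coordinates are those of hg19 in the count tables. Gene biotypes and GC content came from an annotation of a later genome build, matched by symbol, with a biotype for 22103 symbols. Exon length was that given with the deposited counts.

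Totals ranged from 19107171 to 27742406 counts per library. Levels are given as CPM, the usual scaling of counts by library size, here with TMM-scaled sizes, with TMM factors of 1.01 and 0.972 in the wild-type replicates 1 and 2 and 1.07 and 0.950 in the knockout replicates 1 and 2. Genes of low count were removed with filterByExpr by genotype, which left 15027 of 23368. A floor of 3 counts corresponds to 0.114 to 0.155 CPM. Amplified reads are not independent molecules, so intervals and floors cover counting error only. Libraries of the same genotype differed by more than counting error, with a chi-square per degree of freedom of 21.4 between the wild-type libraries and 70.5 between the knockout libraries. The first principal component held 49.8% of the variance and parted the passages.

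Knockout and wild type were compared with edgeR 4.0.16 under R 4.3.3, with robust quasi-likelihood tests of genotype alone and Benjamini-Hochberg adjustment at 0.05. Passage 68 was compared with passage 65 in the same way with genotype as a second term, which leaves 1 residual degree of freedom. Because replicate numbers are tied to passage in the labels, they pair the libraries across genotypes, and a fit with the replicate number as a block was run beside the first. The deviations of same-numbered libraries from their genotype means correlated at 0.355 across genes, which are not independent replicates. An interaction of genotype and passage could not be tested with 1 library per combination.

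The lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, apart from those said here to have been added. The rule named KLF4 and 12 preset germ cell and pluripotency genes. Among protein-coding genes past the threshold, with an average log2 CPM of at least 1 and no overlap between the groups' libraries, it named up to 10 rises and 10 falls between genotypes and 5 of each between passages. Fewer than 3 in a direction were filled up with the smallest p. Each described list gave up to 4 members past the threshold, or else up to 2 with the smallest p. Other genes in the text were chosen after their values were seen. Those are LOC100505876, CEBPZ, RIPK4, IFIH1, IRF9, B2M, LEFTY1 between genotypes, KRT7 and CGA between passages, the blood-cell genes and the genes given by level alone in the closing part.

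The 34 gene lists had 1187 entries, of which 1170 were found in the count tables, and 33 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists. The same test was applied to 23 chromosomes and to 260 windows of 10 Mb with at least 20 tested genes, as separate families.

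The tests were also tried on simulated data, with 5 draws of 200 changed genes among 15027. Without the block, 61.4% of 2-fold and 96.8% of 4-fold changes were called and 9.1% of calls were false. With the block these shares were 87.4%, 99.8% and 4.5%, and for passage 84.8%, 99.6% and 4.3%. A list shifted by 1.5-fold was called in 5 of 5 draws each time, and over the passage draws 2 calls fell on lists that were not shifted. The 200 changed genes had an average log2 CPM of at least 1. Genes were drawn independently, so the draws do not show how camera behaves where the members of a list vary together. In draws without the block, passage entered only through the spread.

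Alternatives were size factors in place of TMM (RLE), library totals alone, no filter, at least 10 counts in every library, DESeq2 1.42.0, limma-voom, the block, other thresholds, an estimated correlation, fry, 5 Mb windows and leaving out each library in turn. With an estimated correlation, camera takes its degrees of freedom from the residual ones, which are few with 4 libraries. Hardly any list or window could pass it here, so failing it is not evidence against a set. Removing RN45S and the MTRNR2L genes, and counts after a loess correction of each library for GC content and gene length (span 0.3), were added after the data were seen. The set of ZNF-named genes and the tests of explanations in the closing part were also formed after the first results. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3.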

Results

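RNA was sequenced from human primordial germ cell-like cells (hPGCLCs), which are made in culture from pluripotent stem cells and stand in for the earliest human germ cells. The cells came from H1, an established human embryonic stem cell line, either wild type or with KLF4 knocked out. KLF4 is a zinc finger transcription factor and 1 of the factors used to reprogram somatic cells to pluripotency. The series title names KLF4 and TFCP2L1 in naive pluripotency and in human germ cell development, and the design sets the 2 genotypes against each other at passage numbers 65 and 68, with 1 library per genotype and passage. The protocol text writes passage days in place of passage number, so whether 65 and 68 count passages or days is uncertain. Each genotype thus has 2 libraries, and replicate 1 is passage 65 and replicate 2 passage 68 in both. The labels do not say whether the libraries came from separate inductions. Each p-value of a gene thus rests on the spread between these 4 libraries, moderated by a spread pooled across genes. In the comparison of genotypes without a block, that spread is the passage difference within each genotype. In the comparison of passages, it is how far the passage difference differs between genotypes. Gene counts summed to 19107171 in wild-type replicate 1, 23670958 in knockout replicate 1, 24043966 in wild-type replicate 2 and 27742406 in knockout replicate 2. The ribosomal RNA precursor RN45S took 30.3%, 25.1%, 31.9% and 34.6% of these totals in the same order. The 95% exact (Clopper-Pearson) intervals of these shares ran from 30.264% to 30.305%, 25.093% to 25.128%, 31.909% to 31.946% and 34.575% to 34.610%, and cover counting error only. After a filter on low counts, 15027 of 23368 genes were tested.

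KLF4 was measured first. Its transcript, on chromosome 9 from 110247133 to 110252047 in hg19, fell in the knockout but was still present. It stood at 79.1 CPM ± 1.49 (SD, n = 2) in wild-type cells and at 28.1 CPM ± 0.759 (SD, n = 2) in knockout cells. The counts of KLF4 were 1508 and 1871 in the wild-type libraries and 726 and 727 in the knockout libraries. The log2 fold change was -1.49 (SE 0.14, 95% interval -1.81 to -1.17), with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0125. The gene counts do not tell an edited transcript from an intact one, and both knockout libraries lay below both wild-type libraries.

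In knockout hPGCLCs, SUCLG2 and CES1 rose, and LOC100505876, ACO1 and KLF4 fell. SUCLG2 encodes a subunit of the GDP-forming succinyl-CoA synthetase of the mitochondrial citric acid cycle. It went from 3.27 CPM ± 1.60 to 35.2 CPM ± 5.15 (SD, n = 2 each), a log2 fold change of 3.44 (SE 0.32) with an edgeR Benjamini-Hochberg adjusted p of 0.0125. CES1, a carboxylesterase best known from liver, went from 0.987 CPM ± 0.299 to 8.55 CPM ± 1.14 (SD, n = 2 each), a log2 fold change of 3.09 (SE 0.34) with an edgeR Benjamini-Hochberg adjusted p of 0.0381. ACO1, the cytosolic aconitase that also acts as iron regulatory protein, fell from 244.2 CPM ± 11.1 to 85.9 CPM ± 5.57 (SD, n = 2 each), a log2 fold change of -1.51 (SE 0.13) with an edgeR Benjamini-Hochberg adjusted p of 0.0125.

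LOC100505876 fell from 33.4 CPM ± 2.60 to 5.72 CPM ± 0.552 (SD, n = 2 each), a log2 fold change of -2.54 (SE 0.19) with an edgeR Benjamini-Hochberg adjusted p of 0.00855. It had no biotype in the gene tables used here, so it stood outside the rule for named genes and was named after its values were seen. It overlaps CEBPZ on the opposite strand. Reads that overlapped exons of both genes were not counted, and the strand of the remaining reads was not used. CEBPZ had a log2 fold change of 0.40 and did not pass. In hg19, SUCLG2 lies on chromosome 3 from 67410884 to 67705038, CES1 on chromosome 16 from 55836764 to 55867075, ACO1 on chromosome 9 from 32384601 to 32450832, and LOC100505876 on chromosome 2 from 37423635 to 37431886. CES1 has close pseudogene copies, so its reads are uncertain where the sequences match. For each of these genes, both knockout libraries lay on the same side of both wild-type libraries.

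These were the only 5 of 15027 genes past an edgeR Benjamini-Hochberg adjusted p of 0.05, with 2 higher and 3 lower. A total of 481 genes (3.20%) had an unadjusted p under 0.05. Under the rule that fills each direction to 3 genes, ZNF254 (log2 fold change 1.60, SE 0.22, edgeR Benjamini-Hochberg adjusted p = 0.154) and DIO3 (-1.21, SE 0.24, edgeR Benjamini-Hochberg adjusted p = 0.999) came next, and neither passed. With the replicate number as a block, which takes the passage difference out of the spread, 55 genes passed, 32 higher and 23 lower, including all 5. The count was 3 with library totals in place of TMM factors, where KLF4 (edgeR Benjamini-Hochberg adjusted p = 0.0566) and CES1 no longer passed, 23 with the block and a correction for GC content and gene length, all 5 among them, 8 with DESeq2, 8 with no filter on low counts, 20 without wild-type replicate 1 and 11 without wild-type replicate 2. With limma-voom CES1 no longer passed (limma-voom adjusted p = 0.157).

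**Figure D1:**
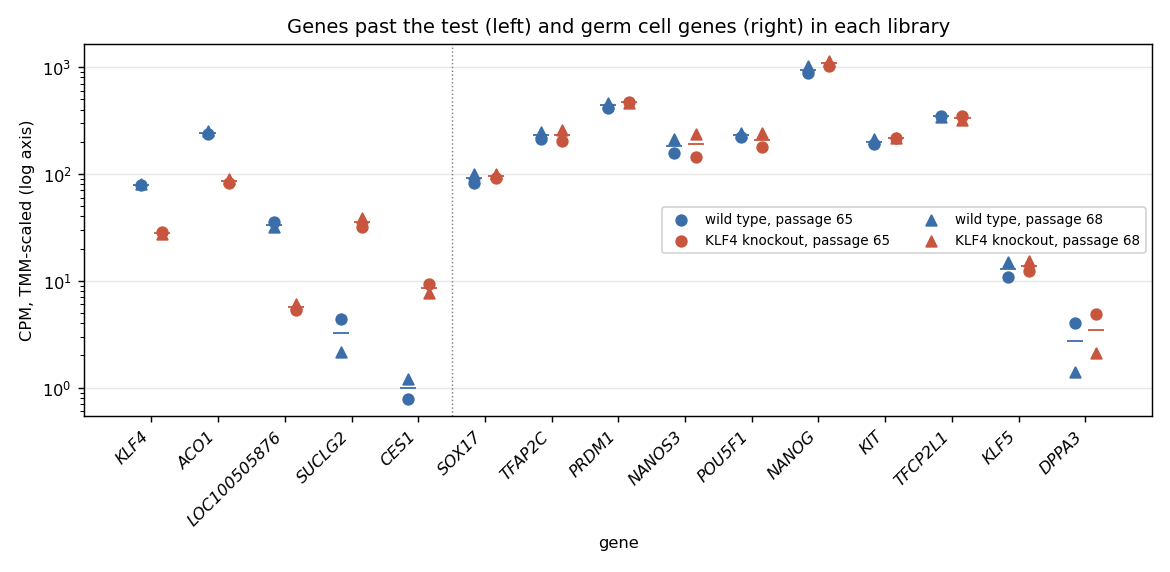
CPM on a log axis for the 5 genes past the test (left of the dotted line) and for 10 germ cell genes (right), with 1 point per library, circles for passage 65, triangles for passage 68 and short lines for the genotype means. The knockout points of KLF4, ACO1 and LOC100505876 lie below the wild-type points and those of SUCLG2 and CES1 above them, while the germ cell genes overlap or lie close together.

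The germ cell program was expressed in both genotypes, and none of its preset members other than KLF4 passed the test. SOX17 and TFAP2C, transcription factors that specify human germ cells, had log2 fold changes of 0.06 (95% interval -0.27 to 0.40) and 0.01 (-0.35 to 0.37). PRDM1, the repressor of somatic genes in germ cells, stood at 439.4 CPM ± 37.6 in wild type and 466.9 CPM ± 8.45 in knockout (SD, n = 2 each), a log2 fold change of 0.09 (95% interval -0.21 to 0.39). NANOS3, an RNA-binding protein of germ cells, had a log2 fold change of 0.05 (95% interval -0.49 to 0.60), and KIT, the receptor for stem cell factor, one of 0.11 (-0.19 to 0.40). NANOG stood at 946.0 CPM ± 106.1 and 1085 CPM ± 81.4 (SD, n = 2 each), with a log2 fold change of 0.20 (95% interval -0.13 to 0.53). POU5F1, whose counts are uncertain because it has close pseudogenes, had a log2 fold change of -0.14 (95% interval -0.53 to 0.24).

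TFCP2L1, the other factor in the series title, stood at 345.2 CPM ± 4.47 in wild type and 334.2 CPM ± 23.2 in knockout (SD, n = 2 each), with a log2 fold change of -0.05 (95% interval -0.34 to 0.25). KLF5, a relative of KLF4, had a log2 fold change of 0.10 (95% interval -0.43 to 0.64). DPPA3, also called STELLA, had one of 0.37, with an interval from -0.90 to 1.64 that does not exclude a 2-fold rise in the knockout. The edgeR Benjamini-Hochberg adjusted p was 0.999 for each of these genes. SOX2 had 0, 2, 0 and 1 counts and KLF17 0, 0, 3 and 3 counts in wild-type replicate 1, knockout replicate 1, wild-type replicate 2 and knockout replicate 2. Both lie at or under a floor of 3 counts per library (0.114 to 0.155 CPM), so no difference was detectable at this depth. Over all genes tested, the 95% interval of the fold change lay within 2-fold either way for 10322 genes (68.7%).

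Preset gene lists were then compared between genotypes. The adjusted p with an estimated correlation, given beside them, rests on few residual degrees of freedom and could hardly fall under 0.05. Of 33 lists, the markers of amnion and trophectoderm stood lowest, with a median log2 fold change of -0.29 over 34 genes, 9 of them positive (camera Benjamini-Hochberg adjusted p = 0.00908, adjusted p = 0.910 with an estimated correlation). The median was -0.40 at passage 65 and -0.06 at passage 68, and without wild-type replicate 1 camera pointed upward (camera Benjamini-Hochberg adjusted p = 0.193). Its members KRT7, a simple-epithelium keratin, and CGA, the glycoprotein hormone alpha subunit, had log2 fold changes of -0.94 and -2.13 without passing the test of single genes. The list of the integrated stress and unfolded protein response was also lower as a set (median -0.09 over 39 genes, camera Benjamini-Hochberg adjusted p = 0.0173, adjusted p = 0.910 with an estimated correlation). In it the VLDLR gene had a log2 fold change of -1.23 and DDIT4, a stress-induced inhibitor of mTORC1, one of -0.53. The immediate early genes were lower as a set (median -0.13 over 27 genes, camera Benjamini-Hochberg adjusted p = 0.0413, adjusted p = 0.910 with an estimated correlation), with EGR2 at -2.37 and ATF3 at -0.79.

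Cytoplasmic ribosomal proteins were higher as a set (median 0.06 over 74 genes, 53 of them positive, camera Benjamini-Hochberg adjusted p = 0.0300, adjusted p = 0.910 with an estimated correlation), with RPL12 at 0.51 and RPS7 at 0.47. Replication-dependent histones were higher as well (median 0.10 over 37 genes, camera Benjamini-Hochberg adjusted p = 0.0370, adjusted p = 0.910 with an estimated correlation), although HIST1H2BM (1.23) and HIST1H3H (-1.76) went opposite ways. In these 5 lists 0 members passed edgeR, DESeq2 or limma-voom over all genes tested, and 0 passed edgeR adjusted over the list alone, while 4, 2, 1, 4 and 2 members, in the order of the lists above, had an unadjusted edgeR p under 0.05. The early germ cell list (34 genes, median 0.03) and the naive pluripotency list (25 genes, median 0.01) did not pass camera, which pointed downward for both although their medians were above 0. KLF4 was the only member of either that passed edgeR, both over all genes and adjusted over the list alone, and it also accounted for the 1 call in the LIF-STAT3 targets. Core pluripotency (27 genes, median 0.10) had 0 members past edgeR, DESeq2 or limma-voom over all genes, 1 with an unadjusted edgeR p under 0.05 and 1 adjusted over the list alone, DPPA4.

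With the replicate block 9 lists passed, those 5 and core pluripotency, Activin-NODAL targets, glycolysis and hypoxia, and S phase, and 0 of 33 passed with the block and an estimated correlation (smallest adjusted p = 0.855, 0 with an unadjusted p under 0.05) or with fry (2 with an unadjusted p under 0.05). The count was 9 without knockout replicate 1 and 8 without wild-type replicate 2. Of the 5, 2 passed without wild-type replicate 1, 3 without knockout replicate 1, 2 without wild-type replicate 2 and 1 without knockout replicate 2. Without wild-type replicate 2 camera pointed downward for the ribosomal proteins (adjusted p = 0.549) and the histones (adjusted p = 0.452). The immediate early genes passed in none of these 4 fits and in neither alternative of the filter on low counts.

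Taking the replicate number as a block brought further genes past the threshold. The pluripotency gene DPPA4 rose by 0.59 on the log2 scale (edgeR with block, Benjamini-Hochberg adjusted p = 0.00699) and LEFTY1, a NODAL antagonist, by 0.75 (edgeR with block, Benjamini-Hochberg adjusted p = 0.0145). KRT7 fell by 0.96 (edgeR with block, Benjamini-Hochberg adjusted p = 0.00137), CGA fell by 2.37 (edgeR with block, Benjamini-Hochberg adjusted p = 0.00532) and DDIT4 fell by 0.53 (edgeR with block, Benjamini-Hochberg adjusted p = 0.0123). RPL12 and RPS7 rose by 0.51 and 0.48, DIO3, the deiodinase that inactivates thyroid hormone, fell by 1.21, and the imprinted gene BLCAP fell by 0.46. DESeq2 with the block called 0 members of the Activin-NODAL, integrated stress and imprinted lists, so LEFTY1, DDIT4 and BLCAP did not pass there. Limma-voom with the block called 1 member of each. Of the ribosomal proteins DESeq2 called 1 and limma-voom 2. ZNF254 rose by 1.60 (edgeR with block, Benjamini-Hochberg adjusted p = 9.64e-06), and 11 of the 32 genes that rose had a ZNF name, as did 491 of 15027 genes tested. After a correction for GC content and gene length, 4 ZNF-named genes passed with the block. Across genes, the log2 ratio of knockout to wild type at passage 65 correlated with that at passage 68 at 0.111, over 15027 genes that are not independent replicates.

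**Figure D2:**
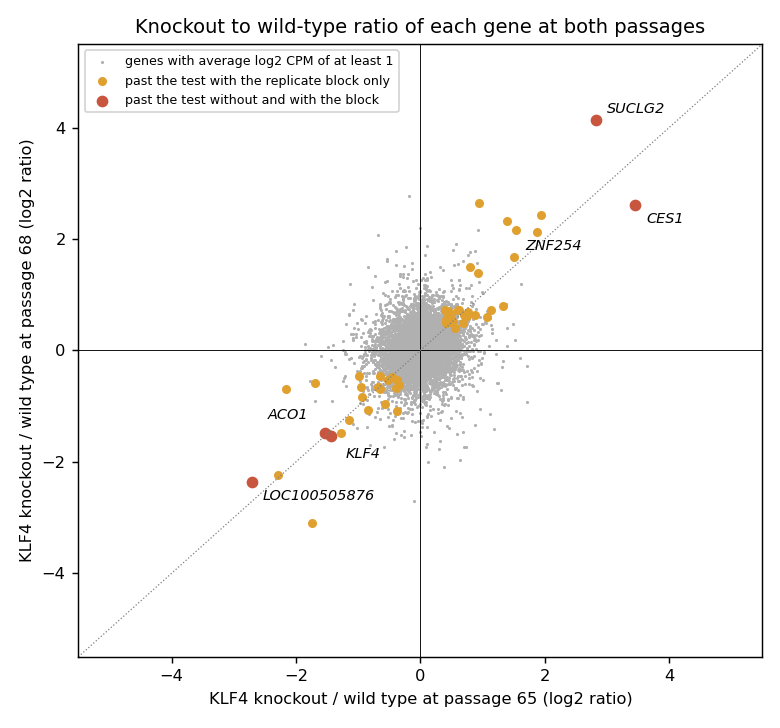
Log2 ratio of knockout to wild type at passage 65 (x axis) and passage 68 (y axis), 1 point for each of 12200 genes with an average log2 CPM of at least 1. The 5 genes past the test without and with the block (red) lie far from 0 on both axes. The 48 genes past it only with the block (orange) lie at various distances, some of them, such as CGA, farther out than KLF4. The rest form a cloud around 0.

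Because an engineered line can differ from its parent in copy number, the same comparison was laid out along the genome. The genes of chromosome 19 from 20 to 30 Mb (hg19) were higher in knockout cells, with a median log2 fold change of 0.31 over 30 genes, 24 of them positive. This stretch holds a cluster of KRAB zinc finger genes, and 24 of its 30 tested genes had a ZNF name, among them ZNF254. The median was 0.38 at passage 65 and 0.27 at passage 68, and the camera Benjamini-Hochberg adjusted p over 260 windows was 6.88e-11 (adjusted p = 0.870 with an estimated correlation). Of the 30 genes, 0 passed edgeR without the block and 3 with it. With the block, a correction for GC content and gene length took the median of the 26 genes with a GC value from 0.31 to 0.19. The genes of chromosome 21 from 40 to 50 Mb were lower, with a median of -0.15 over 74 genes, 50 of them negative (camera Benjamini-Hochberg adjusted p = 0.0195, adjusted p = 0.870 with an estimated correlation). RIPK4, a kinase of epithelial differentiation named here after its values were seen, lies in that window with a log2 fold change of -0.56.

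No other window passed, although 49 of the 260 windows had an unadjusted camera p under 0.05, so the rest were not all flat. Of 23 chromosomes 0 passed camera, with 1 at an unadjusted p under 0.05. The correction for GC content and gene length was not summarized for the chromosome 21 window. Among the 232 genes of chromosome 19 from 50 to 60 Mb (median 0.05), 4 passed edgeR with the block, all higher and with a ZNF name. Chromosome 9, which carries KLF4, had a median of 0.02 over 605 genes. ZNF genes of one cluster are near-identical in parts and reads that align to several places were not counted, so their levels are uncertain. The number of windows and chromosomes past the threshold was 9 without wild-type replicate 1, 1 without knockout replicate 1, 1 without wild-type replicate 2 and 43 without knockout replicate 2, the chromosome 19 window among them each time and the chromosome 21 window in none of these 4 fits.

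**Figure D3:**
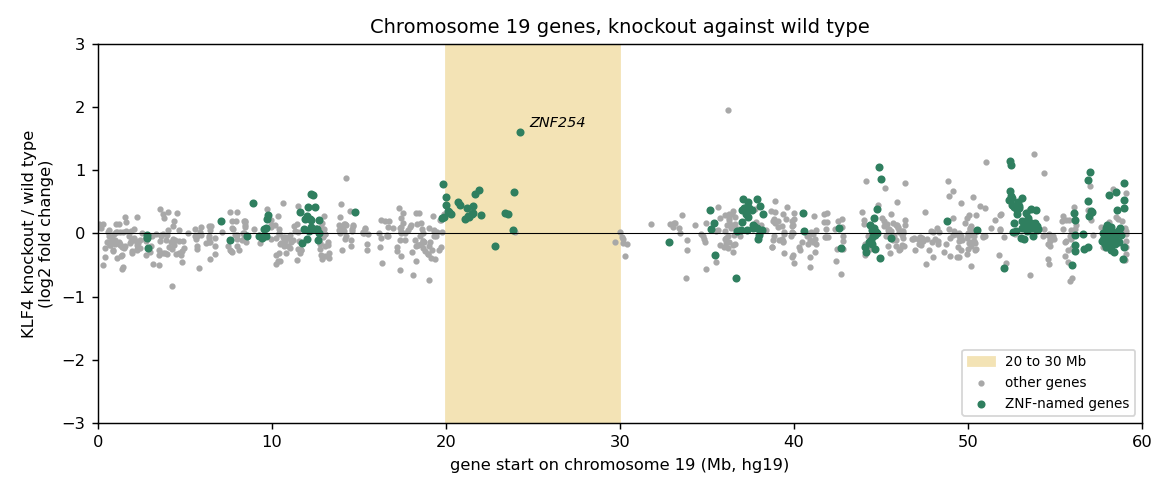
Log2 fold change of knockout against wild type (y axis) by gene start on chromosome 19 in Mb of hg19 (x axis), 1 point for each of 862 genes with an average log2 CPM of at least 1. The 209 ZNF-named genes are green, and between 20 and 30 Mb (shaded) most of them lie above 0.

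The second label of the design is passage number, which is also the replicate number, so passage cannot be told apart from harvest, induction or library preparation. At passage 68 against passage 65, with both genotypes in the test, 23 of 37 tested interferon response genes rose. The list held 46 genes, and the rest, IFIT2, IFI44L and RSAD2 among them, were under the filter on low counts. MX1, which blocks influenza and other viruses, went from 13.6 CPM ± 1.12 to 109.6 CPM ± 20.7 (SD, n = 2 each), a log2 fold change of 3.003 (SE 0.121) with an edgeR Benjamini-Hochberg adjusted p of 8.56e-16. XAF1, IFIT1 and OAS1 rose by 2.92, 2.88 and 2.44 on the log2 scale, IFI6 by 2.38 and OAS2 by 3.33. IFIH1, which encodes the RNA sensor MDA5, rose by 2.31, and the transcription factor IRF9 by 1.15. IFIH1 and IRF9 were named after their values were seen.

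Of these 37 genes, none of the other 14 passed over all genes tested in either direction, and 28 were called when adjusted over the list alone. The median log2 fold change of the list was 1.15 (camera Benjamini-Hochberg adjusted p = 1.09e-51), and it was 1.13 within wild type and 1.07 within knockout, which are values without a test. The adjusted p was 0.651 with an estimated correlation. B2M, the light chain of MHC class I, did not pass, with a log2 fold change of -0.76.

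Markers of amnion and trophectoderm moved the opposite way. Of 34 tested, 16 fell, no member rose and 22 were called when adjusted over the list alone, with a median of -0.77 (camera Benjamini-Hochberg adjusted p = 7.61e-18, adjusted p = 0.651 with an estimated correlation). WNT6 fell by 3.29, KRT23 by 2.96, VGLL1 by 2.04 and HEY1, a NOTCH target, by 1.73 on the log2 scale. KRT7 fell by 0.62 and CGA by 1.66. The median of the amnion and trophectoderm list was -0.91 within wild type and -0.55 within knockout, values without a test. The BMP targets overlap this group, and 6 of 25 fell over all genes as well as adjusted over the list alone, among them HEY1, MSX1 (-1.68), DLX5 (-0.83) and HAND1 (-0.73). Their median was -0.26 (camera Benjamini-Hochberg adjusted p = 7.09e-04, adjusted p = 0.651 with an estimated correlation).

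Mesenchymal and mesodermal genes were lower too, more so within wild type. The fibroblast and mesenchyme median was -0.43 within wild type and -0.13 within knockout, where 10 of 26 were positive. For primitive streak and mesoderm it was -0.71 within wild type and -0.22 within knockout, where 11 of 24 were positive. These are values without a test. Of 26 fibroblast and mesenchyme genes, 8 fell and 3 rose, with 16 called when adjusted over the list alone (median -0.40, camera Benjamini-Hochberg adjusted p = 6.32e-05, adjusted p = 0.651 with an estimated correlation). Among them the collagen gene COL3A1 went from 60.9 CPM ± 22.5 to 15.96 CPM ± 0.559 (SD, n = 2 each), COL5A2 fell by 1.77, COL6A3 by 1.30 and the matrix proteoglycan LUM by 2.09 on the log2 scale. Of 24 primitive streak and mesoderm genes, 7 fell, including the WNT antagonist DKK1 (-2.74) and HAND2 (-2.71), and 14 were called when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.00230, adjusted p = 0.651 with an estimated correlation). Among protein-coding genes with an average log2 CPM of at least 1, which leaves out WNT6 and other genes of lower level, the 5 with the largest falls were ZEB2, a driver of epithelial to mesenchymal transition (-3.15), RSPO2, which strengthens WNT signalling (-2.90), SLC39A2 (-2.79), PAPPA (-2.59) and SORCS1 (-2.36). Neuroectoderm genes did not pass camera, with DLK1 and TUBB3 rising by 0.78 and 0.52 and OTX1 falling by 1.95, and neither did endoderm genes, of which 2 rose (GATA4 among them) and 4 fell, AFP by 3.04.

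Germ cell genes were slightly higher at passage 68. In the early germ cell list NANOS3, GATA4 and VENTX rose by 0.57, 0.56 and 0.52 on the log2 scale and DPPA3 fell by 1.34. These 4 were called over all genes and 10 were called when adjusted over the list alone, with a median of 0.14 over 34 genes (camera Benjamini-Hochberg adjusted p = 0.00250, adjusted p = 0.651 with an estimated correlation). LEFTY2 went from 13.9 CPM ± 5.92 to 57.0 CPM ± 7.91 (SD, n = 2 each) and LEFTY1 rose by 0.99. Both belong to the Activin-NODAL targets, of which 3 rose and 1 fell. That list had a median of 0.17 over 17 genes, with 8 called when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 0.00329, adjusted p = 0.651 with an estimated correlation).

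Core pluripotency passed camera upward (median 0.07 over 27 genes, camera Benjamini-Hochberg adjusted p = 0.0448, adjusted p = 0.651 with an estimated correlation), with LEFTY2 and LEFTY1 rising, LIN28B falling by 0.52 and 8 called when adjusted over the list alone, and with library totals in place of TMM factors its median was -0.05, against -0.12 for all genes. The primed pluripotency list was lower (4 of 29 fell, 1 rose and 10 were called when adjusted over the list alone, median -0.42, camera Benjamini-Hochberg adjusted p = 0.00329, adjusted p = 0.651 with an estimated correlation).

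Genes of the G2 phase and mitosis were lower, with 9 of 40 falling and 13 called when adjusted over the list alone (median -0.25, camera Benjamini-Hochberg adjusted p = 2.07e-09, adjusted p = 0.651 with an estimated correlation). HMMR fell by 0.98, G2E3 by 0.78, ECT2 by 0.66 and TOP2A, the mitotic DNA topoisomerase, by 0.60 on the log2 scale. Of 74 cytoplasmic ribosomal protein genes 11 fell, led by RPS3A (-1.16), RPL39 (-0.76) and RPL9 (-0.75), and 15 were called when adjusted over the list alone (median -0.05, camera Benjamini-Hochberg adjusted p = 0.00161, adjusted p = 0.874 with an estimated correlation). Their median was -0.18 within wild type and 0.04 within knockout, where 41 of 74 were positive, which are values without a test. Replication-dependent histones were lower as a set (4 of 37 fell over all genes and over the list alone, median -0.28, camera Benjamini-Hochberg adjusted p = 0.00329, adjusted p = 0.817 with an estimated correlation), with medians of -0.53 within wild type and -0.07 within knockout. Cell adhesion and epithelial genes (8 of 42 fell, 14 over the list alone, median -0.11, camera Benjamini-Hochberg adjusted p = 0.00173), p53 targets (3 of 31 fell, 5 over the list alone, median -0.08, camera Benjamini-Hochberg adjusted p = 0.0480) and cholesterol biosynthesis genes (3 of 29 fell, 9 over the list alone, median -0.12, camera Benjamini-Hochberg adjusted p = 0.0484) also passed downward, each with an adjusted p = 0.651 with an estimated correlation.

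In all, 1040 of 15027 genes passed between the passages, 408 higher and 632 lower, and 235 of them changed at least 2-fold (edgeR quasi-likelihood with genotype as a term and Benjamini-Hochberg adjustment at 0.05). Of 33 lists 15 passed camera, 4 upward and 11 downward. With an estimated correlation 0 passed and 0 had an unadjusted camera p under 0.05. That test rests on 1 residual degree of freedom, and in it the interferon list went from an unadjusted camera p of 3.30e-53 to 0.0753. It could hardly have called any list, so it does not decide whether the lists shifted. A correction for GC content and gene length left 541 calls, 486 of them among the 1040. DESeq2 called 310 genes and edgeR without the genotype term 313, and each of these called 7 amnion and trophectoderm genes. With library totals in place of TMM factors the median of all genes moved to -0.12 and the calls split into 112 higher and 841 lower, while 18 interferon genes still rose and 20 amnion and trophectoderm genes fell.

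**Figure D4:**
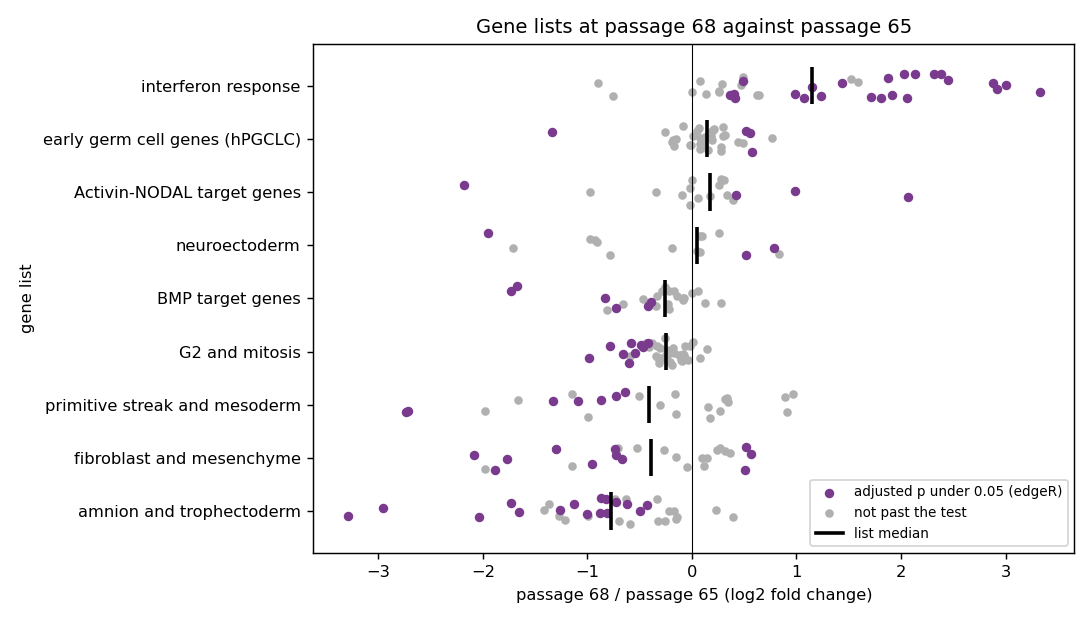
Log2 fold change of passage 68 against passage 65 (x axis) for the tested members of 9 gene lists (rows), 1 point per gene, purple where the edgeR adjusted p was under 0.05 and grey otherwise, with a black bar at each list's median. Interferon response genes lie furthest right, with a median of 1.15, and amnion and trophectoderm genes furthest left, with a median of -0.77.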

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

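None of the values in this part has a test of its own, and they were picked out because the ratio of knockout to wild type had opposite signs at the 2 passages. The difference between passages was not tested, since there is 1 library per genotype and passage, and several of the ratios are close to 0.

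The log2 ratio of knockout to wild type for SOX17 was 0.16 at passage 65 and -0.01 at passage 68, a difference of -0.17. For PRDM1 it was 0.20 and -0.02, a difference of -0.21, and for TFCP2L1 0.01 and -0.11, a difference of -0.12. TFAP2C went the other way, from -0.04 to 0.05, a difference of 0.10, as did NANOS3, from -0.10 to 0.16, a difference of 0.26.

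The median ratio of the cytoplasmic ribosomal protein genes was -0.05 at passage 65 and 0.18 at passage 68, a difference of 0.23. That of the replication-dependent histones was -0.04 and 0.29, a difference of 0.33. Both lists passed camera upward in the comparison of genotypes over all 4 libraries (adjusted p = 0.910 for each with an estimated correlation), and their medians were above 0 at passage 68 and below 0 at passage 65.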

How the results depend on the processing

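Removing RN45S and the MTRNR2L genes, the counts after a GC and length correction, and the counts of list members under each setting, were chosen after the results were seen. The 5 genes of the knockout comparison became 3 with library totals only, 8 with no filter on low counts, 8 with DESeq2, 55 with the replicate block and 23 with the block and a GC and length correction, and ranged from 6 to 20 over the fits leaving out 1 library, where the lone library of a genotype is assumed to vary like the rest. KLF4 kept its direction in every setting run, with log2 fold changes from -1.53 to -1.46 over the 4 fits leaving out 1 library and -1.44 with the block and the GC and length correction, and missed the threshold only with library totals (-1.46, edgeR Benjamini-Hochberg adjusted p = 0.0566). The 5 lists past camera became 0 with an estimated correlation, 0 with fry and 9 with the block, and ranged from 4 to 9 without 1 library. The 2 windows became 0 with an estimated correlation and 4 with 5 Mb windows, and ranged from 1 to 43 without 1 library. The 1040 genes between passages became 541 with the GC and length correction, 310 with DESeq2, 313 without the genotype term, 1625 at an adjusted p under 0.1 and 235 at a fold of at least 2, and the 15 lists became 0 with an estimated correlation. The 16 amnion and trophectoderm calls became 7 with DESeq2, 7 without the genotype term and 8 at a fold of at least 2. Interferon calls lay between 17 and 25 in all settings run, all upward. Another threshold and a fold minimum change a count by construction. The block takes the passage difference out of the spread, and the common dispersion of the knockout comparison was 0.0128 with it against 0.0347 without. The cause of the other shifts was not tested. Of single named genes other than KLF4 under the alternatives, 0 reversed past the threshold, while in the passage comparison 124 values no longer passed and in the knockout comparison 2 no longer passed (CES1, with library totals and limma-voom) and 15 newly passed. A further 46 values in the knockout comparison moved by more than their SE without passing, and without 1 library 64 to 66 of 69 genes that had not passed kept their sign. Leaving out 1 library could not be run as a test for the passage comparison, which then has no residual degrees of freedom. Depth leaves genes under about 3 counts per library undecided. The estimated correlation leaves camera too few residual degrees of freedom to call a list or window here, so its counts of 0 decide nothing.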

Other observations

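The tests of a gain of the whole of chromosome 19, of a batch tied to passage and of a lower share of other cell types were chosen only after the results were seen. The other tests were set before their own values were computed. The patterns that all of them address were found in these same data. The levels in this part are means over all 4 libraries with their SD, unless a passage is named.

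The cells expressed the early germ cell program at high levels and late germ cell genes hardly at all. Of 34 early germ cell genes 31 stood at 10 CPM or more and 18 at 100 or more, among them the integrin ITGA6 (2022 CPM ± 125.0, n = 4) and the surface protein PDPN (930.8 CPM ± 61.2, n = 4). Of 37 later germ cell genes 28 stood under 1 CPM. The germ cell RNA helicase DDX4 had 0 counts, which allows up to 3 counts per library (0.114 to 0.155 CPM), and DAZL had 1 count in all. REC8, a meiotic cohesin subunit, stood at 24.6 CPM ± 6.05 (n = 4), TDRD5 at 6.87 CPM ± 0.212 (n = 4) and DMC1 at 4.05 CPM ± 0.475 (n = 4).

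Among genes of DNA methylation, the 5-methylcytosine oxidase TET1 (439 CPM ± 72.4, n = 4) and the maintenance methyltransferase DNMT1 (135.8 CPM ± 6.60, n = 4) were expressed, as were the de novo enzymes DNMT3A (78.0 CPM ± 5.99, n = 4) and DNMT3B (24.6 CPM ± 3.42, n = 4), and DNMT3L was at 0.472 CPM ± 0.302 (n = 4). CPM is not divided by transcript length, so levels of different genes are not ranked here. In the KLF and SP family, SP1 (192.0 CPM ± 7.10, n = 4) and KLF7 (142.6 CPM ± 32.3, n = 4) were above 100 CPM, and KLF2 stood at 1.13 CPM ± 0.450 (n = 4). Among imprinted genes, PEG10 stood at 1550 CPM ± 106 (n = 4) and GNAS at 754 CPM ± 37.4 (n = 4), and PEG3 had 0 counts, again up to the same floor.

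ZNF-named genes were higher in knockout libraries, with a median log2 fold change of 0.08 over 491 genes, 63.5% of them positive (unadjusted camera p of 3.47e-05, and 0.135 with an estimated correlation). They were not a preset list and were taken up from these same data, so that p is not independent support. After a correction for GC content and gene length the median was 0.0473, against 0.0822 before (unadjusted camera p of 0.00121). With the block, 4 in place of 11 genes then passed edgeR, and the chromosome 19 window median went from 0.31 to 0.19. The rule against GC content and gene length as the sole cause was met. However, the correction moved genes by a median of 0.0573 either way, more than the 0.0473 left. An incomplete correction could leave such a remainder, so no conclusion is drawn. A gain of the whole of chromosome 19 is argued against, since its 840 genes without a ZNF name had a median of -0.0324 against 0.107 for its 233 ZNF-named genes (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest they can give). Gains of parts of it stay open. ZNF-named genes elsewhere had a median of 0.0664 (unadjusted camera p of 0.0177, and 0.168 with an estimated correlation), upward but under the bound of 0.1 set beforehand. The 6 other genes of 20 to 30 Mb had a median of -0.0609, which met the rule set beforehand against a gain of that window. However, 4 of them lay under an average log2 CPM of 1, a limit that rule did not hold, so no conclusion is drawn from them. Reads shared between these near-identical genes were not tested, and an effect of the genotype stays open and untested.

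Interferon-stimulated genes were higher at passage 68. Blood or immune cells are argued against, since 15 general blood-cell genes had a median of 0.128 CPM at passage 68, 11 of them under 1 CPM, while the 37 tested interferon genes had a median of 9.86 CPM. The blood-cell genes were not filtered on counts, and the interferon genes were. Of the markers expressed, CD74 stood at 13.9 CPM and LCP1 at 137.0 CPM at passage 68, with log2 fold changes from passage 65 of 0.43 for CD74 (edgeR Benjamini-Hochberg adjusted p = 0.188) and -0.46 for LCP1 (edgeR Benjamini-Hochberg adjusted p = 0.00557). GC content and gene length are argued against as well, with a corrected median of 1.14 (unadjusted camera p of 9.73e-29 at the preset correlation, while the uncorrected list had an adjusted p = 0.651 with an estimated correlation) and 22 in place of 23 genes past edgeR. A batch of harvest or library preparation cannot be told apart from passage for the 23 genes that rose, because the labels give none that crosses passage, and an effect of passage itself stays open and untested.

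Amnion and trophectoderm genes were lower at passage 68. Whether the share of all other cell types fell alike could not be decided. The median of the list differed by -0.73 from that of neuroectoderm, endothelial and blood, endoderm, mesenchyme and mesoderm genes together (30 against 92 genes, two-sided permutation test with 100000 resamples, p = 0.00145). But the list was taken up for its low median in these same data, and the permutation treats the genes of a list as independent. A lower share of amnion-like and mesenchymal cells together stays open, since the fibroblast and mesenchyme list had a median of -0.40 (two-sided permutation p = 0.0529 for the difference from amnion and trophectoderm) and primitive streak and mesoderm genes outside the amnion list one of -0.16 (permutation p = 0.0442). GC content and gene length are argued against, with a corrected median of -0.83 (unadjusted camera p of 5.36e-20 at the preset correlation, while the uncorrected list had an adjusted p = 0.651 with an estimated correlation), although 11 in place of 16 genes then passed edgeR. Fewer amnion-like cells, lower expression within cells and a harvest batch may each account for it, and the labels do not separate them.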
